A study of Mus musculus with 90 samples.

How the data were processed

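Bulk RNA was measured in 90 mouse BMDM libraries, 5 for each of 18 groups formed by 6 treatments and 3 times. Per the labels' protocols, bones of several wild-type mice were pooled for each replicate and marrow cells were cultured with M-CSF before treatment. Libraries were made with a QuantSeq 3' kit with unique molecular identifiers and sequenced on a NovaSeq instrument. Per the submitters' processing notes, reads were quantified with Salmon against the GRCm39 genome build, and the Salmon version was not given in the sources used here. The deposited values were estimated counts per gene, and 83.7% of them were whole numbers. Log2 CPM values were deposited as well. These differed by at most 6e-04 from log2 CPM recomputed here with edgeR (TMM factors, prior count 2), and were not used further. The data held 56980 features, with 148 symbols shared by more than 1 feature, so features were kept apart by identifier. Estimated counts were rounded to whole numbers before testing.

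Library totals ran from 1.11 to 6.63 M counts, with a mean of 5.10 M in DMSO 1 h and 2.81 M in MSU 22 h. Each time was fitted alone with its 30 libraries and 6 groups in edgeR 4.0.16 (limma 3.58.1, R 4.3.3, data.table version 1.17.8). Genes were kept with the edgeR default filter, libraries were scaled with TMM factors, dispersions were estimated with a trend, and groups were compared with quasi-likelihood F tests. This left 12066, 11850 and 12078 tested genes at 1, 7 and 22 h. Each stressor was compared with DMSO at each time, and at 22 h also with each other stressor. The dependence on time was tested for each stressor with an interaction F test (2 degrees of freedom) on its 15 libraries and the 15 DMSO libraries. Benjamini-Hochberg adjustment was made over all tested genes of a comparison, and genes with an adjusted p below 0.05 were called. A gene's standard error was its log2 fold change divided by the square root of its F value. Replicates on the same side were counted as the treated libraries lying on the called side of the mean CPM of the other group.

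The comparisons, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. The 33 lists covered lysosomal hydrolases, lysosomal membrane proteins, V-ATPase subunits, autophagy, MiT/TFE factors with mTORC1 feedback genes, lysosome damage with ESCRT repair, and phosphoinositide kinases and phosphatases. They also covered cholesterol biosynthesis and uptake, fatty acid synthesis, LXR targets, iron handling, metallothioneins with zinc genes, hypoxia (HIF) targets, the integrated stress response (ATF4), the ER unfolded protein response, NRF2 targets, heat shock and p53 targets. The others were NF-kB and inflammatory cytokines, inflammasome and pyroptosis, the interferon response, immediate early genes, the cell cycle, mitochondrially encoded mRNAs, and markers of macrophage identity, lipid-associated macrophages, osteoclasts and fusion, neutrophils and granulocyte precursors, dendritic cells, lymphocytes, mast cells and basophils, fibroblasts and stroma, and erythroid cells and platelets. Lists were written from general knowledge of these pathways, and those with at least 3 tested genes were tested with camera on voom weights, with the correlation between genes estimated for each list. Camera p were adjusted over the lists of a comparison, and called members were also counted after adjustment over the list alone.

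Genes were named by a rule with 5 parts. For comparisons with DMSO these were the called genes with the largest absolute change, up to 6 per direction at 7 and 22 h and 3 at 1 h, with a mean of at least 8 CPM, all 5 treated libraries on the same side and a symbol other than a gene model name. For lists with at least 3 called members, up to 4 members of the more frequent direction and 2 of the other were eligible. Between stressors up to 3 genes per direction, and across times the 5 genes with the smallest p, were eligible, together with 26 fixed genes such as Gdf15, Rragd, Abca1 and Csf1r. For genes named by the size of their change, 5 of 5 libraries on the same side was required and is no separate result. Genes leading the component within groups were named after their values were seen.

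The library-type score of a library was the mean log2 CPM, less its mean over all libraries, of the 50 genes with the largest loadings on the first principal component of the values left after group means were removed, for genes with a mean log2 CPM of at least 4. Group means were removed to choose these genes but not from the score, so the score can also hold treatment effects. Libraries were split into higher and lower at a score of -0.374, a gap found after the data were seen. Transcript lengths came from a GENCODE M21 (GRCm38) annotation, matched by gene identifier for 98.2% of the tested genes at 1 h, and no coordinates of that build were used. For the overlap of stressors, counts without any treatment effect were simulated 20 times for all 30 libraries at 22 h, and the DMSO libraries were split in 10 ways between the members of a pair. The labels gave replicate numbers without stating that equal numbers shared cells, so groups were compared without pairing and the number was tried as a block.

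Alternatives fixed beforehand were DESeq2 1.42.0 with its own size factors (adjusted p of NA left as NA), RLE factors, no filter on low counts, a stricter filter of 5 CPM in 5 libraries, and the replicate number as a block. Fits of only the libraries compared, or of all 90 libraries for the tests across times, were also made. Each library was also left out in turn, and gene lists were tested with camera at a preset correlation of 0.01, with fry and with the block. Alternatives chosen after the data were seen were the library-type score as a covariate, fits within higher-score libraries and, at 1 h, within lower-score libraries, and fits at 22 h and across times without the 3 libraries under 2 M counts. The called genes of each comparison were set against those found when the same libraries were split into groups in other ways.

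Each fit was tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 genes changed per stressor by 1.5, 2 or 4 fold. At 1 h the recovered share for BafA1, U18666A, VPS34IN-1, E/L/P and MSU against DMSO was 34.3, 34.3, 41.8, 40.3 and 47.8% at 1.5 fold, 74.6, 74.6, 73.1, 79.1 and 70.1% at 2 fold and 95.5, 93.9, 98.5, 93.9 and 87.9% at 4 fold, with 4.9, 4.26, 5.33, 5.96 and 6.16% of the calls false. At 7 h the recovered share for BafA1, U18666A, VPS34IN-1, E/L/P and MSU against DMSO was 55.2, 73.1, 59.7, 62.7 and 52.2% at 1.5 fold, 79.1, 77.6, 92.5, 86.6 and 80.6% at 2 fold and 95.5, 100, 100, 98.5 and 100% at 4 fold, with 4.97, 2.91, 5.62, 7.3 and 3.12% of the calls false. At 22 h the recovered share for BafA1, U18666A, VPS34IN-1, E/L/P and MSU against DMSO was 46.3, 52.2, 53.7, 49.3 and 44.8% at 1.5 fold, 77.6, 82.1, 82.1, 86.6 and 67.2% at 2 fold and 95.5, 89.4, 95.5, 95.5 and 92.4% at 4 fold, with 3.95, 3.87, 6.1, 6.1 and 5.56% of the calls false. For the tests across times of BafA1, U18666A, VPS34IN-1, E/L/P and MSU it was 22.4, 40.3, 37.3, 35.8 and 28.4% at 1.5 fold, 59.7, 59.7, 70.1, 61.2 and 62.7% at 2 fold and 87.9, 90.9, 92.4, 87.9 and 90.9% at 4 fold, with 0.877, 3.79, 4.32, 8.21 and 7.63% of the calls false. Between stressors it ran from 43.1 (U18666A against MSU) to 60.4% (BafA1 against U18666A) at 1.5 fold, from 69.9 (BafA1 against MSU) to 84.8% (VPS34IN-1 against E/L/P) at 2 fold and from 91.3 (U18666A against VPS34IN-1) to 96.9% (BafA1 against E/L/P) at 4 fold, with 2.25 (BafA1 against E/L/P) to 6.21% (BafA1 against MSU) of the calls false. A list shifted by 0.5 log2 was called up by camera in all 15 comparisons with DMSO, with at most 1 other list called. Genes were drawn independently of each other in these simulations. The list result therefore does not show how camera performs where genes of a list vary together, as in the real libraries. The simulated libraries also lacked the component within groups that underlies the library-type score. The shares of false calls therefore do not give the rate of false calls in real libraries that differ along it, as at 1 h.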

Results

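Bone marrow-derived macrophages (BMDMs), grown from wild-type mouse bone marrow with M-CSF, were treated with 5 lysosomal stressors and profiled by 3' RNA sequencing with molecular identifiers. The stressors were bafilomycin A1 (BafA1, 25 nM), which blocks the lysosomal proton pump, and U18666A (6 uM), which blocks cholesterol export from lysosomes. The others were VPS34IN-1 (2 uM), an inhibitor of the lipid kinase VPS34, the protease inhibitors E64, leupeptin and pepstatin together (E/L/P, 50 uM each), and monosodium urate crystals (MSU, 200 ug/mL). DMSO served as the control for all 5 stressors, and cells were collected after 1, 7 or 22 h. The question was how the transcriptional response differs between forms of lysosomal stress and over time. Each of the 18 groups held 5 libraries, 1 per biological replicate, and the bones of several mice were pooled for each replicate. The 90 libraries held 4.72 M estimated counts in the median, from 1.11 to 6.63 M. The 3 libraries under 2 M were U18666A 22 h replicate 3 (1.27 M), MSU 22 h replicate 2 (1.28 M) and MSU 22 h replicate 3 (1.11 M). Fold changes below are log2 values ± SE from edgeR, with 5 libraries per group, and a gene is said to rise or fall only where its Benjamini-Hochberg adjusted p was below 0.05. Gene lists fixed before the data were examined were tested with camera, using a correlation between genes estimated for each list. In parentheses after a list, 'list alone' gives the genes called after adjustment over that list alone, and the adjusted p is from camera.

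Libraries of one group differed along a component that took 36.5% of the variance within groups. Its 50 leading genes, among them Gnb2, Rusc2 and Llgl1, gave each library a library-type score. The score fell into higher and lower values, with 14 higher and 16 lower libraries at 1 h, 26 and 4 at 7 h, and 29 and 1 at 22 h. At 1 h the DMSO group had 4 higher and 1 lower library, the E/L/P group 1 and 4, the BafA1, VPS34IN-1 and MSU groups 2 and 3 each, and the U18666A group 3 and 2. Across genes, which are not independent replicates, the 1 h fold changes correlated with the loadings of this component at r = -0.83 for BafA1, -0.63 for U18666A, -0.61 for VPS34IN-1, -0.82 for E/L/P and -0.41 for MSU. The counts of called genes at 1 h are therefore given also with the score as a covariate and within each library type, settings chosen after the data were seen. Where 1 type held a single library of a group, that library was assumed to vary as the others did.

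**Figure D1:**
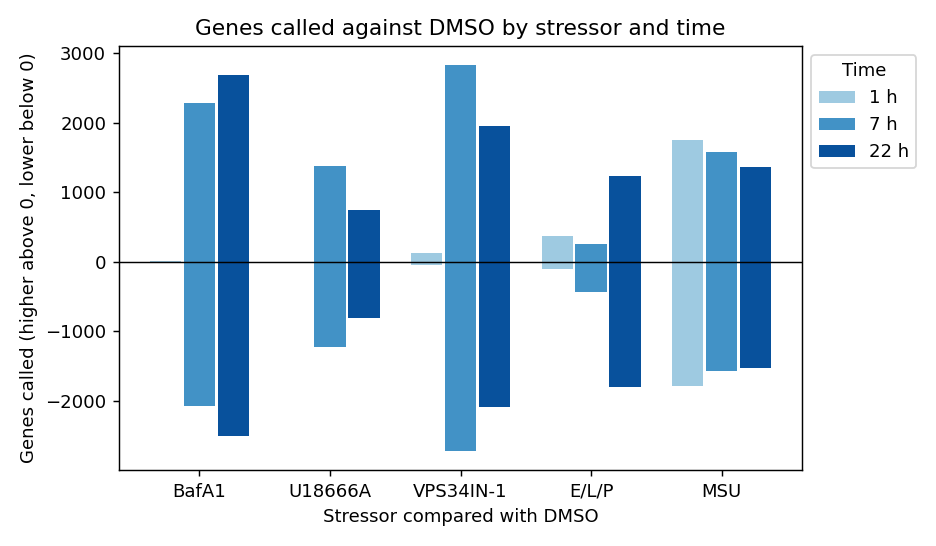
Number of genes called in each comparison with DMSO (edgeR, adjusted p below 0.05), drawn above 0 where higher and below 0 where lower under the stressor, with bars for 1, 7 and 22 h. BafA1 and VPS34IN-1 went from 15 and 170 genes at 1 h to 4346 and 5546 at 7 h, while MSU had 3536 at 1 h.

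After 1 h of BafA1, Gdf15, a stress-induced cytokine of the TGF-beta family, rose from 67.8 ± 13 to 204 ± 34.7 CPM (mean ± SD, n = 5 and 5), a log2 fold change of 1.59 ± 0.20. Gadd45b, a stress-inducible gene of the GADD45 family, rose by 1.02 ± 0.17. The AP-1 gene Fos (-1.59 ± 0.12), the MAP kinase phosphatase gene Dusp1 (-1.23 ± 0.23), Btg2 (-1.03 ± 0.19) and the inflammatory cytokine gene Il1b (-1.63 ± 0.34) fell. Of 29 tested immediate early genes, 6 fell and 1 rose (list alone 1 up, 13 down), with a median of -0.44 and a camera adjusted p of 0.0113. In all, 15 of 12066 tested genes were called, 7 higher and 8 lower. For the 6 named genes the edgeR adjusted p was at most 0.037, with 5 of 5 treated libraries on the called side of the DMSO mean. With the score as a covariate 20 genes were called and Gdf15 rose by 1.34. Within higher-score libraries 21 were called (Gdf15 1.38), and within lower-score libraries, where DMSO had 1 library, 2 (Gdf15 1.48). Il1b did not pass within higher-score libraries (adjusted p 0.326), in a fit of only the 10 libraries compared (0.211) or in 8 of the 10 fits that left out 1 library. Dusp1 did not pass in the fit of only these libraries (0.0699) or in 5 of the 10 left-out fits, nor did Btg2 in 2. Within lower-score libraries Fos passed, and the other 5 named genes did not. The count was 7 in a fit of only the 10 libraries compared, 234 with no filter on low counts (35 higher and 199 lower), and between 4 (without DMSO 1 h replicate 4) and 14 when single libraries were left out. The immediate early genes stayed called with the covariate (adjusted p 0.00365), and lost the call in 2 of the 10 fits that left out 1 library (highest without BafA1 1 h replicate 1, adjusted p 0.178).

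U18666A called 6 genes at 1 h, 3 higher and 3 lower. Gdf15 (1.30 ± 0.20), Gadd45b (1.17 ± 0.17) and Ccrl2, an atypical chemokine receptor gene (0.98 ± 0.18), rose. The genes that fell were Fos (-1.15 ± 0.12), Id1 (-0.98 ± 0.17), an inhibitor of DNA binding, and the pseudokinase gene Trib1 (-0.68 ± 0.11). The edgeR adjusted p was at most 0.0179, with 5 of 5 libraries on the same side, and no gene list was called by camera. The count was 24 with the score as a covariate (Gdf15 1.11), 182 within higher-score libraries (3 against 4; Gdf15 1.11) and 1 within lower-score libraries (2 against 1; Gdf15 1.38). DESeq2 called 16 genes, 12 higher and 4 lower, and with no filter on low counts 96 were called (27 higher and 69 lower). Ccrl2 did not pass in 5 of the 10 fits that left out 1 library, Id1 in 2, and Trib1 in a fit of only the 10 libraries compared (adjusted p 0.104). Within lower-score libraries none of the 6 passed.

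With VPS34IN-1 at 1 h, Gdf15 (1.55 ± 0.20) and Gadd45b (1.40 ± 0.17) rose and Fos fell (-1.88 ± 0.13), as with BafA1 and U18666A. Atp1b1, the beta-1 subunit of the sodium pump (-1.85 ± 0.36), and Id1 (-1.22 ± 0.17) fell. The class I MHC gene H2-K2 had the largest rise (2.47 ± 0.37), and counts of such near-identical class I genes are uncertain. Of 34 tested ATF4 and integrated stress response genes 3 rose (list alone 7 up, 0 down), among them Ppp1r15a (1.15 ± 0.17) and the transcription factor gene Ddit3 (0.93 ± 0.19). The list was not called by camera (adjusted p 0.51). Of 12066 tested genes, 121 rose and 49 fell, with an edgeR adjusted p of at most 0.00833 for the named genes and 5 of 5 libraries on the same side. With the score as a covariate 280 genes were called (Gdf15 1.36), within higher-score libraries 166 (2 against 4; Gdf15 1.21) and within lower-score libraries 9 (3 against 1; Fos -1.86). Leaving out single libraries gave 71 (without DMSO 1 h replicate 4) to 183 genes. No filter on low counts gave 279, of which more fell than rose (117 higher and 162 lower). Ddit3 did not pass within higher-score libraries (adjusted p 0.0705), and within lower-score libraries only Fos, Gadd45b and Gdf15 passed among the named genes.

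Protease inhibition with E/L/P at 1 h lowered the MAP kinase phosphatase gene Dusp6 (-1.60 ± 0.40), Atp1b1 (-1.54 ± 0.35) and Idi1 of the cholesterol pathway (-1.17 ± 0.34). Gdf15 (0.68 ± 0.20), Gadd45b (0.95 ± 0.17) and the proliferation marker Mki67 (1.13 ± 0.21) rose, as did the adaptor gene Sh2b2 (1.30 ± 0.15). Of 29 immediate early genes 5 fell and 1 rose (list alone 2 up, 9 down), with a camera adjusted p of 0.38, and no list was called. In total 369 genes rose and 108 fell of 12066 tested (edgeR adjusted p at most 0.0475 for the named genes, 5 of 5 libraries on the same side). DESeq2 called 450 higher and 282 lower. With the score as a covariate 193 genes were called, 141 of them among the 477. The count was 59 within higher-score libraries (1 against 4) and 2 within lower-score libraries (4 against 1), in fits of fewer libraries. With the covariate the log2 fold change was -0.66 for Dusp6, -1.58 for Atp1b1, 0.32 for Gdf15 and 0.89 for Mki67. Of these genes, Gdf15 (adjusted p 0.272) did not pass with the covariate, nor did Idi1 (0.304). Gdf15 did not pass with RLE scaling either (0.052). Within higher-score libraries Mki67 was at 0.24 (adjusted p 0.736), Gadd45b at 0.47 (0.356) and Atp1b1 at -1.58 (0.053), none of which passed, while Sh2b2 and Dusp6 passed. Within lower-score libraries none of the named genes passed. Of the 10 fits that left out 1 library, Idi1 did not pass in 8, Gdf15 in 6, Dusp6 in 5 and Atp1b1 in 2. Dusp6, Gdf15 and Idi1 did not pass in a fit of only the 10 libraries compared either (adjusted p 0.075, 0.12 and 0.0928). Leaving out single libraries gave from 109 (without DMSO 1 h replicate 3) to 1591 genes (without DMSO 1 h replicate 1), and a fit of only the 10 libraries compared 44. No filter on low counts gave 1462 genes and turned the balance (362 higher and 1100 lower).

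MSU changed 3536 genes within 1 h, 1758 higher and 1778 lower. The balance of higher and lower genes depended on the setting, with 968 higher and 1996 lower under no filter on low counts, 1771 and 1714 under the stricter filter, and 2201 and 2162 with the covariate. The lysosomal hyaluronidase gene Hyal1 (1.56 ± 0.20), Syne2, which encodes a protein of the nuclear envelope (1.55 ± 0.26), Mki67 (1.48 ± 0.21) and the NRF2 target Osgin1 (1.32 ± 0.20) rose. Snhg6, a host gene of small nucleolar RNA (-1.98 ± 0.28), Lsm5 (-1.75 ± 0.25), Snord13 (-1.60 ± 0.25) and the chemokine gene Cxcl2 (-1.24 ± 0.32) fell. The V-ATPase and autophagy lists split in direction. Of 18 V-ATPase subunits 7 fell, such as Atp6v1g1 (-1.02 ± 0.13), and 2 rose, such as Tcirg1 (0.73 ± 0.11; list alone 2 up, 8 down). Of 40 autophagy genes 7 fell, such as Gabarapl2 (-1.21 ± 0.30), and 5 rose (list alone 5 up, 7 down). Among one-sided lists, p53 targets fell in 7 of 17 (list alone 0 up, 7 down, adjusted p 0.133) and cholesterol genes in 6 of 25 (list alone 0 up, 6 down, adjusted p 0.809). Lipid-associated macrophage genes fell in 5 of 19 (list alone 0 up, 5 down, adjusted p 0.809). No list was called by camera (adjusted p of at least 0.133). Fold changes rose with transcript length, with a rank correlation across genes of 0.23, against 0.095 to 0.17 for the other stressors at 1 h. The edgeR adjusted p of the named genes was at most 0.00387, with 5 of 5 libraries on the same side. With the score as a covariate 4363 genes were called (Hyal1 1.53, Snhg6 -2.04), and within higher-score libraries 3232 (2 against 4). Within lower-score libraries 746 were called (3 against 1; Hyal1 2.02, Snhg6 -2.90). In that fit Cxcl2 (-0.47, adjusted p 0.474), Syne2 (0.83, adjusted p 0.271), Gabarapl2 (-0.69, adjusted p 0.303), Lsm5 (-1.17, adjusted p 0.0854) and Osgin1 (1.12, adjusted p 0.0606) did not pass.

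By 7 h BafA1 had raised Acod1, whose enzyme makes itaconate, from 1.77 ± 0.897 to 42.5 ± 9.61 CPM (mean ± SD, n = 5 and 5), a log2 fold change of 4.61 ± 0.20. Rapgef3, the cyclic AMP sensor gene EPAC1 (4.18 ± 0.21), the C-type lectin gene Clec4e (3.63 ± 0.13) and Fabp4, a fatty acid binding protein gene (3.50 ± 0.14), also rose. The chemokine receptor genes Ccr2 (-4.30 ± 0.32), Ccr3 (-3.40 ± 0.30) and Cx3cr1 (-3.16 ± 0.14) fell, with Cytip (-3.90 ± 0.14) and the mRNA-decay gene Zfp36l1 (-3.41 ± 0.14). Among lysosomal genes, 21 of 39 membrane protein genes rose and 3 fell (list alone 22 up, 4 down, adjusted p 0.000386). The channel gene Mcoln1 rose (1.18 ± 0.15), while Tpcn1 fell (-1.06 ± 0.09). V-ATPase subunits rose in 14 of 18 (list alone 15 up, 0 down, adjusted p 0.00424), for example Atp6v0d2 (1.71 ± 0.11). Hydrolase genes rose in 24 of 48 with 6 lower (list alone 24 up, 7 down, adjusted p 0.0265), for example Gla (1.38 ± 0.06). The mTORC1-linked GTPase gene Rragd rose by 3.14 ± 0.12.

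Hypoxia (HIF) targets formed the list with the smallest camera p for BafA1 at 7 h: 30 of 33 rose and 1 fell (list alone 30 up, 1 down), with a median of 1.02 and a camera adjusted p of 2.24e-05. They included the glycolytic genes Pfkfb3 (2.55 ± 0.11) and Hk2 (2.31 ± 0.08) and the growth factor gene Vegfa (1.09 ± 0.11). Integrated stress response genes rose in 30 of 34 (list alone 30 up, 0 down, adjusted p 6.24e-05), with the cystine transporter gene Slc7a11 at 3.36 ± 0.14, Gdf15 at 2.92 ± 0.12 and Trib3 at 1.65 ± 0.13. Of 25 cholesterol genes 17 rose (list alone 17 up, 0 down, adjusted p 0.00976). Of 21 unfolded protein response genes 18 rose (list alone 18 up, 0 down, adjusted p 0.0131), such as Hspa5 (0.95 ± 0.07). Of 27 immediate early genes 16 fell and 7 rose (list alone 7 up, 18 down, adjusted p 0.0207), with Fos at -2.81 ± 0.12. LXR targets fell in 7 of 13 (list alone 0 up, 7 down, adjusted p 0.0265), among them the cholesterol exporter gene Abca1 (-2.19 ± 0.13). Of 27 macrophage identity genes 18 fell, such as Mertk (-2.16 ± 0.12), and 4 rose (list alone 4 up, 18 down, adjusted p 0.0265). The autophagy (adjusted p 0.0308), lysosome damage (0.0308) and MiT/TFE (0.0484) lists were called up. Each lost its call when single libraries were left out, with highest adjusted p of 0.0562, 0.0625 and 0.0831. Over all 11850 tested genes, 2279 rose and 2067 fell, and the edgeR adjusted p of the genes named here was at most 1.79e-10, with 5 of 5 libraries on the same side.

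U18666A at 7 h raised cholesterol synthesis and uptake genes: 20 of 25 rose and none fell (list alone 20 up, 0 down), with a median of 1.19 and a camera adjusted p of 3.31e-05. Examples were the squalene synthase gene Fdft1 (1.78 ± 0.15), Insig1 (1.72 ± 0.13) and Idi1 (1.62 ± 0.26). LXR targets fell in 5 of 13 and rose in 1 (list alone 1 up, 5 down, adjusted p 0.0375), led by Abca1 (-2.22 ± 0.13) and Abcg1 (-1.18 ± 0.15), with Scd2 rising (0.70 ± 0.17). Of 39 lysosomal membrane genes 18 rose and 3 fell (list alone 20 up, 5 down, adjusted p 0.000664). Of 18 V-ATPase subunits 13 rose (list alone 14 up, 0 down, adjusted p 0.00564), such as Atp6v1c1 (0.87 ± 0.06). Fabp4 (2.67 ± 0.14), Rapgef3 (2.48 ± 0.26), the integrin gene Itgb3 (1.99 ± 0.24) and Rragd (1.77 ± 0.13) rose, and Cytip (-2.21 ± 0.12) and Ccr2 (-2.17 ± 0.25) fell. The small nuclear RNAs Rn7sk (-2.63 ± 0.11) and Scarna2 (-2.36 ± 0.15) also fell, though a library made from poly(A) RNA measures such transcripts uncertainly. The p53 target list was called down (6 of 18 down, 1 up, list alone 1 up, 6 down, adjusted p 0.0332). Immediate early genes were called down and the hydrolase, integrated stress response, unfolded protein response, fatty acid synthesis, metallothionein, hypoxia, iron handling and lysosome damage lists up. Their camera adjusted p was 0.0375 for hydrolases and 0.048 for the other 8, and each of the 9 lost its call without some single library (highest adjusted p 0.0571 to 0.0831). Of 11850 tested genes 1384 rose and 1217 fell, and the named genes had an edgeR adjusted p of at most 0.00249, with 5 of 5 libraries on the same side.

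VPS34IN-1 changed the most genes at 7 h, 5546 of 11850, with 2828 higher and 2718 lower. Integrated stress response genes rose in 30 of 34 and fell in 1 (list alone 31 up, 1 down, median 1.20, adjusted p 0.000108). Among them were Slc7a11 (4.97 ± 0.13), Gdf15 (4.45 ± 0.13), Trib3 (2.87 ± 0.12) and Ddit3 (2.27 ± 0.10). Rapgef3 (5.85 ± 0.19), Clec4e (4.27 ± 0.13), Ccrl2 (3.93 ± 0.13) and Rragd (3.79 ± 0.12) rose. Conversely, Cx3cr1 (-4.51 ± 0.16), Fos (-3.80 ± 0.13), Gpr183 (-3.59 ± 0.14) and the signalling adaptor gene Dok2 (-3.56 ± 0.18) fell. Of 39 lysosomal membrane genes 24 rose, such as Clcn7 (1.43 ± 0.10), and 6 fell (list alone 24 up, 7 down, adjusted p 0.00384). Of 18 V-ATPase subunits 14 rose, such as Atp6v0d2 (1.92 ± 0.11), and 1 fell (list alone 14 up, 2 down, adjusted p 0.0357). Macrophage identity genes fell in 19 of 27 and rose in 4 (list alone 4 up, 19 down, adjusted p 0.0357). Inflammasome genes fell in 11 of 16 and rose in 1 (list alone 1 up, 11 down, adjusted p 0.0357). Immediate early genes fell in 15 of 27 and rose in 7 (list alone 8 up, 15 down, adjusted p 0.0454). Examples were Nlrp3 (-1.44 ± 0.13) and Egr1 (-2.97 ± 0.20). Pik3c3, which encodes VPS34 itself, fell (-0.33 ± 0.09), though not within higher-score libraries (adjusted p 0.0793). The last 3 lists and the V-ATPase subunits lost their call when single libraries were left out, with highest adjusted p of 0.0537, 0.0537, 0.0656 and 0.0506. The named genes had an edgeR adjusted p of at most 0.00291, with 5 of 5 libraries on the same side.

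E/L/P gave the smallest response at 7 h, with 261 genes higher and 436 lower of 11850. No filter on low counts turned this balance (429 higher and 293 lower). Integrated stress response genes rose in 9 of 34 (list alone 14 up, 0 down, adjusted p 0.00794), led by the asparagine synthetase gene Asns (0.83 ± 0.12), Eif4ebp1 (0.50 ± 0.10) and Atf4 (0.42 ± 0.08). Immediate early genes fell in 8 of 27 (list alone 0 up, 8 down, adjusted p 0.00765), such as Egr1 (-0.59 ± 0.14) and Klf2 (-0.56 ± 0.12). The nuclear RNA Neat1 (1.37 ± 0.31) and Hyal1 (1.00 ± 0.19) rose, and Rn7sk (-0.75 ± 0.10) fell. The called genes named here had an edgeR adjusted p of at most 0.0113, with 5 of 5 libraries on the same side. The count was 229 within higher-score libraries, where Neat1 (adjusted p 0.0867), Egr1 (0.11) and Klf2 (0.0979) did not pass. It lay between 365 (without E/L/P 7 h replicate 1) and 772 when single libraries were left out, with 456 without DMSO 7 h replicate 3, 374 without DMSO 7 h replicate 4 and 379 without E/L/P 7 h replicate 3.

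MSU at 7 h raised 24 of 34 integrated stress response genes and lowered 1 (list alone 27 up, 2 down, median 0.46, adjusted p 0.00262). Among them were Gdf15 (1.81 ± 0.12), Slc7a11 (1.39 ± 0.16), Ppp1r15a (1.04 ± 0.18) and Trib3 (1.04 ± 0.14). No other list was called. Rapgef3 (2.05 ± 0.29), Hyal1 (1.89 ± 0.18), Cipc (1.44 ± 0.14) and Fabp4 (1.41 ± 0.15) rose, with the chemokine gene Ccl3 (1.23 ± 0.13) and the interleukin 1 receptor antagonist gene Il1rn (1.20 ± 0.12). Scarna2 (-2.06 ± 0.15), Snord13 (-1.95 ± 0.24), Rn7sk (-1.84 ± 0.11) and Il1b (-1.20 ± 0.36) fell. In total 1584 genes rose and 1573 fell of 11850, and the named genes had an edgeR adjusted p of at most 0.0117, with 5 of 5 libraries on the same side.

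**Figure D2:**
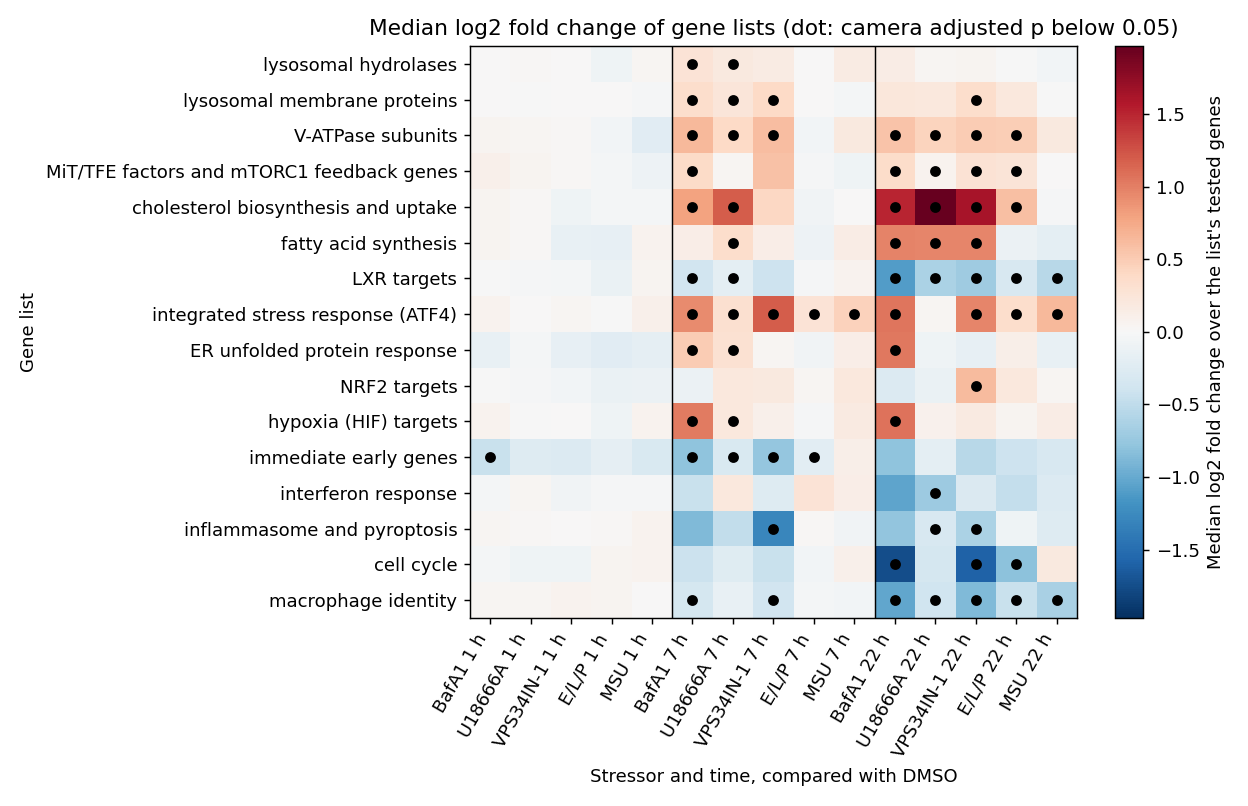
Median log2 fold change over the tested genes of 16 gene lists (vertical axis) in each stressor and time against DMSO (horizontal axis), with a dot where camera called the list at an adjusted p below 0.05. The integrated stress response was called in all 5 stressors at 7 h, and cholesterol genes reached a median of 1.97 with U18666A at 22 h against -0.02 with MSU.

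After 22 h of BafA1, hypoxia targets stayed high, with 28 of 33 higher and 2 lower (list alone 28 up, 2 down), a median of 1.07 and a camera adjusted p of 2.23e-06. Examples were the collagen prolyl hydroxylase gene P4ha2 (2.50 ± 0.22) and the lactate transporter gene Slc16a3 (2.03 ± 0.12). Acod1 (5.14 ± 0.23), Clec4e (4.81 ± 0.18), Itgb3 (4.75 ± 0.20) and the cell cycle inhibitor gene Cdkn1c (4.54 ± 0.25) rose. The chemokine receptor gene Ccr3 (-5.86 ± 0.34), the thrombospondin gene Thbs1 (-5.59 ± 0.33) and the neutrophil granule gene Ngp (-4.97 ± 0.56) fell. Cholesterol genes rose in 22 of 25 (list alone 23 up, 0 down, adjusted p 0.00388), with Mvd at 3.73 ± 0.19. Fatty acid synthesis genes rose in 12 of 17 (list alone 12 up, 0 down, adjusted p 0.0209), with Fasn at 2.39 ± 0.17. LXR targets fell in 9 of 13 and rose in 1 (list alone 1 up, 9 down, adjusted p 0.00388). Of 34 integrated stress response genes 28 rose and 1 fell (list alone 30 up, 1 down, adjusted p 0.000417), with Phgdh at 2.99 ± 0.24. Unfolded protein response genes rose in 19 of 21 (list alone 19 up, 0 down, adjusted p 0.00388), with Hyou1 at 1.57 ± 0.15. Of 18 V-ATPase genes 16 rose and 1 fell (list alone 17 up, 1 down, adjusted p 0.00467), with Atp6v1g1 at 1.26 ± 0.14. The MiT/TFE list was called up, with 11 of 19 higher and 3 lower (list alone 12 up, 3 down, adjusted p 0.0289), and Rragd rose by 2.95 ± 0.11. All 40 cell cycle genes fell (list alone 0 up, 40 down, adjusted p 0.0072), for example Rrm2 (-2.66 ± 0.21). Macrophage identity genes fell in 22 of 27 and rose in 1 (list alone 1 up, 24 down, median -1.03, adjusted p 7.34e-05). They included Cx3cr1 (-4.36 ± 0.20) and Csf1r, the M-CSF receptor gene (-1.03 ± 0.11). Over 12078 tested genes 2683 rose and 2505 fell, and the named genes had an edgeR adjusted p of at most 6.15e-09, with 5 of 5 libraries on the same side.

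U18666A at 22 h raised every one of the 25 tested cholesterol genes (list alone 25 up, 0 down), with a median of 1.97 and a camera adjusted p of 1.59e-06. Idi1 rose from 14.2 ± 2.86 to 122 ± 36.2 CPM (mean ± SD, n = 5 and 5; log2 fold change 3.11 ± 0.30). Mvd (2.77 ± 0.19), Fdps (2.61 ± 0.17), Cyp51 (2.59 ± 0.12) and Hmgcs1 (2.30 ± 0.08), enzymes of the same pathway, rose as well. Fatty acid synthesis genes rose in 14 of 17 (list alone 14 up, 0 down, adjusted p 3e-04), such as Fads2 (2.11 ± 0.23). LXR targets fell in 5 of 13 and rose in 1 (list alone 1 up, 9 down, adjusted p 0.000394), led by Abca1 (-3.13 ± 0.15) and Abcg1 (-2.30 ± 0.18). V-ATPase subunits rose in 15 of 18 (list alone 16 up, 0 down, adjusted p 0.000379). Macrophage identity genes fell in 13 of 27 and rose in 3 (list alone 3 up, 17 down, adjusted p 0.00213), such as C1qa (-1.26 ± 0.17). Lipid-associated macrophage genes rose in 8 of 19 and fell in 2 (list alone 9 up, 3 down, adjusted p 0.0412), with Fabp4 at 1.70 ± 0.15 and Gpnmb at 1.14 ± 0.08. This call ended with the score as a covariate (0.0771). Interferon response genes fell in 20 of 38 (list alone 0 up, 27 down, adjusted p 0.0412), such as Ifit1 (-1.49 ± 0.33). The interferon call was lost when some single library was left out (highest adjusted p 0.065), as were those of the MiT/TFE, metallothionein and inflammasome lists (each 0.0478). The integrated stress response list was not called (adjusted p 0.513, median 0.04), although Gdf15 rose (1.75 ± 0.18). In total 753 genes rose and 811 fell of 12078, and the called genes named here had an edgeR adjusted p of at most 0.00147, with 5 of 5 libraries on the same side.

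VPS34IN-1 at 22 h raised Itgb3 (5.00 ± 0.20), Bex1 (4.88 ± 0.23), Cdkn1c (4.78 ± 0.25) and the glutathione transferase gene Gsta3 (3.60 ± 0.19). It lowered Ccr3 (-5.99 ± 0.34), the pentraxin gene Nptx1 (-5.74 ± 0.21) and Cx3cr1 (-5.25 ± 0.21). NRF2 targets rose in 16 of 23 and fell in 2 (list alone 17 up, 2 down, adjusted p 0.00296). Rising targets included Slc7a11 (4.04 ± 0.17), which is also an ATF4 target, Gstm1 (2.28 ± 0.11) and Srxn1 (1.60 ± 0.15), while Hmox1 fell (-0.46 ± 0.15). Integrated stress response genes rose in 26 of 34 (list alone 28 up, 0 down, adjusted p 0.000239), with Atf5 at 3.00 ± 0.12. Cholesterol genes rose in 21 of 25 (list alone 22 up, 0 down, adjusted p 0.00281). Of 17 fatty acid synthesis genes 14 rose (list alone 15 up, 0 down, adjusted p 0.00296), with Scd2 at 1.80 ± 0.17. V-ATPase subunits rose in 14 of 18 (list alone 14 up, 0 down, adjusted p 0.00296), with Atp6v1c1 at 1.26 ± 0.08. The MiT/TFE (9 up and 2 down of 19, list alone 9 up, 3 down, adjusted p 0.0115) and metallothionein lists (3 of 6 up, list alone 3 up, 1 down, adjusted p 0.0279) were called up. The lysosomal membrane list was called up as well (19 up and 3 down of 39, list alone 23 up, 3 down, adjusted p 0.0394), but not in 2 of the 10 fits that left out 1 library (highest adjusted p 0.0512). All 40 cell cycle genes fell (list alone 0 up, 40 down, adjusted p 0.00296), such as Uhrf1 (-2.96 ± 0.32). Of 27 macrophage identity genes 22 fell and 2 rose (list alone 2 up, 22 down, adjusted p 0.000216), with Aif1 at -3.40 ± 0.21. Of 13 LXR targets 8 fell and 2 rose (list alone 2 up, 10 down, adjusted p 0.00583), with Abca1 at -3.20 ± 0.15. Of 15 inflammasome genes 11 fell and 2 rose (list alone 2 up, 12 down, adjusted p 0.0307), with Nlrp3 at -1.96 ± 0.13. Over all tested genes 1949 rose and 2092 fell, and the named genes had an edgeR adjusted p of at most 0.0128, with 5 of 5 libraries on the same side.

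E/L/P at 22 h lowered Atp1b1 from 11.8 ± 8.50 to 0.474 ± 0.375 CPM (mean ± SD, n = 5 and 5; log2 fold change -4.60 ± 0.70). It also lowered Cx3cr1 (-2.28 ± 0.17) and the matrix gene Tgfbi (-1.79 ± 0.12). Integrated stress response genes rose in 17 of 34 (list alone 19 up, 0 down, adjusted p 0.00401), led by Gdf15 (2.34 ± 0.18), the serine synthesis gene Phgdh (2.19 ± 0.25) and Trib3 (1.53 ± 0.15). Of 18 V-ATPase subunits 13 rose (list alone 13 up, 0 down, adjusted p 0.00401), such as Atp6v1h (0.86 ± 0.16). Of 25 cholesterol genes 16 rose (list alone 17 up, 0 down, adjusted p 0.0202), such as Idi1 (1.88 ± 0.30). Lysosome damage genes rose in 7 of 30 and fell in 2 (list alone 7 up, 2 down, adjusted p 0.0202), with the galectin gene Lgals3 at 0.76 ± 0.09. The MiT/TFE list was called up (8 up and 3 down of 19, list alone 9 up, 3 down, adjusted p 0.0241), with Rragd at 1.22 ± 0.12. Cell cycle genes fell in 33 of 40 and rose in 1 (list alone 1 up, 36 down, adjusted p 0.0202), with Mki67 at -1.60 ± 0.24. Of 13 LXR targets 6 fell (list alone 0 up, 7 down, adjusted p 0.0113), such as Abca1 (-1.65 ± 0.14). Of 27 macrophage identity genes 16 fell and 2 rose (list alone 2 up, 17 down, adjusted p 0.0165), with Csf1r at -0.96 ± 0.11. The cathepsin genes Ctsd (0.39 ± 0.08), which rose, and Ctsl (-0.12 ± 0.11), which did not pass, encode proteases of the kinds that E/L/P inhibits. In total 1238 genes rose and 1794 fell of 12078, and the called genes named here had an edgeR adjusted p of at most 0.00035, with 5 of 5 libraries on the same side. Fitted on the 10 libraries compared alone, 4691 genes were called.

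MSU at 22 h lowered 21 of 27 macrophage identity genes and raised 1 (list alone 1 up, 23 down, median -0.63, adjusted p 2.92e-05). Examples were Cx3cr1 (-2.28 ± 0.18), C1qa (-1.79 ± 0.17) and Csf1r (-1.02 ± 0.12). Integrated stress response genes rose in 22 of 34 (list alone 24 up, 0 down, adjusted p 0.000312), with Trib3 at 2.44 ± 0.15, Gdf15 at 2.40 ± 0.18 and Ddit3 at 1.59 ± 0.18. LXR targets fell in 8 of 13 (list alone 0 up, 9 down, adjusted p 0.000323), such as Apoe (-1.02 ± 0.12). Cholesterol genes were not called (2 up and 0 down of 25, list alone 2 up, 0 down, adjusted p 0.995). Cdkn1c (3.84 ± 0.25), Bex1 (3.19 ± 0.26), Itgb3 (2.51 ± 0.23) and the autophagy receptor gene Sqstm1 (1.18 ± 0.07) rose. The small nuclear RNA Scarna2 (-3.27 ± 0.33) and Zfp36l1 (-1.99 ± 0.12) fell. In total 1366 genes rose and 1521 fell of 12078, and the called genes named here had an edgeR adjusted p of at most 6.99e-08, with 5 of 5 libraries on the same side.

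The effect of each stressor was next compared across the 3 times, with an edgeR F test of the interaction of treatment and time on the 30 libraries of that stressor and DMSO. The effect differed between times for 4171 genes with BafA1, 1943 with U18666A, 5682 with VPS34IN-1, 4037 with E/L/P and 2995 with MSU. These tests include the 1 h libraries, whose types fell unevenly on the groups, so part of these counts may follow library type. With the score as a covariate the counts were 5290, 2531, 6150, 2845 and 3163 in the same order. Within higher-score libraries they were 4203, 1924, 5133, 3330 and 2189. For BafA1, Cytip moved from -0.08 at 1 h to -3.90 at 7 h and -4.84 at 22 h (adjusted p = 9.64e-20), and Hk2 from 0.07 to 2.31 and 1.71 (1.74e-18). Abca1 under U18666A moved from -0.01 to -2.22 and -3.13 (3.68e-16), and Hmgcs1 from 0.04 to 1.49 and 2.30 (1.86e-14). VPS34IN-1 left the chemokine gene Ccl9 at -0.11 and -0.20 before a fall to -3.62 (2.26e-21), and Nptx1 at 0.10 and -0.43 before -5.74 (2.26e-21). Clec4e peaked at 7 h (-0.09, 4.27 and 1.79, 6.98e-19). Tgfbi under E/L/P stood at -0.04, 0.01 and -1.79 (4.69e-12), and the integrin gene Itgav at 0.09, -0.24 and -1.48 (7.92e-10). With MSU the integrin genes Itgb5 (0.36, -0.27 and -1.28, 4.96e-11) and Itgal (0.32, -0.28 and -1.55, 1.18e-10) went from higher to lower log2 fold changes over time. All p in these sentences are Benjamini-Hochberg adjusted edgeR values.

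Stressors were compared with each other at 22 h, with the 5 libraries of each. BafA1 had more Acod1 than U18666A (4.71 ± 0.23), E/L/P (4.71 ± 0.22) and MSU (4.03 ± 0.23). Clec4e was higher in BafA1 than in U18666A (4.60 ± 0.18), VPS34IN-1 (3.02 ± 0.16) and E/L/P (4.11 ± 0.17). BafA1 also had more of the mitochondrial adenylate kinase gene Ak4 than U18666A (3.42 ± 0.24) and MSU (3.57 ± 0.26). The iron exporter gene Slc40a1 (-3.07 ± 0.17) and the interferon-induced gene Ifit1 (-2.77 ± 0.32) were lower in BafA1 than in VPS34IN-1, and Nptx1 was higher (3.27 ± 0.24). VPS34IN-1 had more Slc7a11 than E/L/P (3.69 ± 0.17) and MSU (2.90 ± 0.17), and U18666A had less than VPS34IN-1 (-3.51 ± 0.17). Atp1b1 was lower in E/L/P than in MSU (-3.34 ± 0.84, not passing without MSU 22 h replicate 4, adjusted p 0.0667). It was higher than in E/L/P in BafA1 (5.63 ± 0.65), U18666A (5.31 ± 0.67) and VPS34IN-1 (4.49 ± 0.70). U18666A exceeded E/L/P in Fads2 (2.96 ± 0.25) and exceeded MSU in Idi1 (3.13 ± 0.32), while Trib3 was lower than in MSU (-2.16 ± 0.15). The edgeR adjusted p of these genes was at most 3.32e-13, 6.38e-08, 1.67e-08 and 1.27e-12 for BafA1 against U18666A, VPS34IN-1, E/L/P and MSU. It was at most 7.74e-17, 2.02e-06 and 2.34e-08 for U18666A against VPS34IN-1, E/L/P and MSU. For VPS34IN-1 against E/L/P and MSU and for E/L/P against MSU it was at most 7.19e-06, 1.71e-14 and 0.00324. Of the first group, 5 of 5 libraries lay on the called side of the mean of the second.

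**Figure D3:**
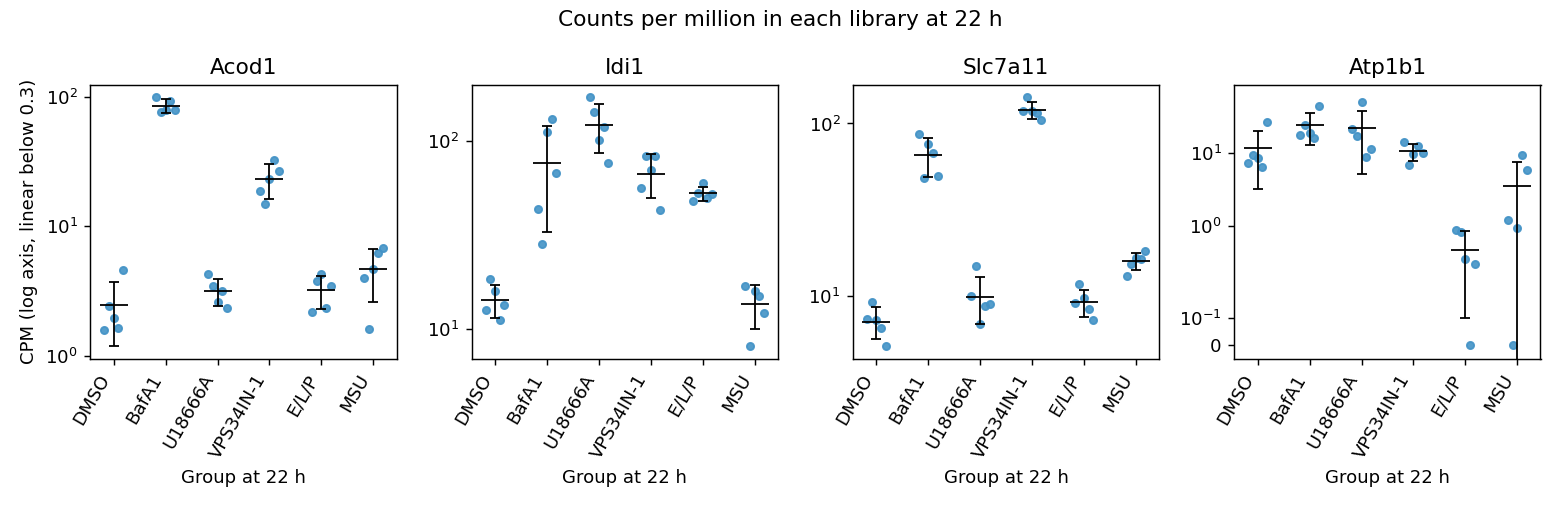
CPM (log axis) of Acod1, Idi1, Slc7a11 and Atp1b1 in each of the 30 libraries at 22 h, by group, with points for libraries and black marks for the mean with SD. Atp1b1 was lower in E/L/P than in DMSO (log2 fold change -4.60), and Idi1 was higher in U18666A (3.11).

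Called genes between stressors at 22 h numbered 3925 for BafA1 against U18666A, 2693 against VPS34IN-1, 4711 against E/L/P and 4796 against MSU. U18666A differed from VPS34IN-1 in 2232 genes, from E/L/P in 788 and from MSU in 2716. VPS34IN-1 differed from E/L/P in 3248 and from MSU in 4356, and E/L/P from MSU in 3339. Fitted on only the 10 libraries compared, the counts were 2546 for BafA1 against U18666A, 2841 for BafA1 against MSU, 1473 for U18666A against MSU and 5252 for VPS34IN-1 against E/L/P. U18666A against E/L/P gave 1186 genes within higher-score libraries, 463 without E/L/P 22 h replicate 4, 507 without E/L/P 22 h replicate 5 and 511 without U18666A 22 h replicate 5.

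At 22 h 604 genes were called in the same direction by all 5 stressors, 217 higher and 387 lower. Lists of these sizes drawn independently would share 0.858 genes, and 20 simulations of unchanged groups against shared controls gave 0. The first value leaves out the shared DMSO libraries and the second the treatment effects, so neither accounts for both. A count with a separate DMSO library for each stressor was not made. The shared falls included Ccr3, Ccr2, Cx3cr1, Abca1, Cytip and Zfp36l1, where the smallest of the 5 log2 falls was -1.72, -1.58, -1.41, -1.49, -1.48 and -1.41. Small RNAs such as Rn7sk (-2.23 to -1.08) and Scarna2 (-3.27 to -1.02) were also among them, though libraries from poly(A) RNA measure these uncertainly. Gene models counted as separate genes fell too, such as Gm54754 (-2.32 to -1.09), whose changes were close to those of Rn7sk. Gdf15 (1.75 to 3.31), Itgb3 (1.42 to 5.00), Rragd (1.18 to 2.95), Gpnmb (0.54 to 1.66) and Atp6v0d2 (0.48 to 1.38) rose in all 5 at 22 h, and Csf1r fell in all 5 (-1.12 to -0.54). Between pairs of stressors, 819 (U18666A and MSU) to 3065 genes (BafA1 and VPS34IN-1) were called the same way and 10 to 165 in opposite ways, against 187 to 867 for independent lists and 0 in the simulated groups. Because all stressors shared the same DMSO libraries, fold changes of unchanged groups correlated at r = 0.46 to 0.52 across genes in the simulation, against 0.43 (VPS34IN-1 and MSU) to 0.79 (BafA1 and VPS34IN-1) in the data. With different DMSO libraries for each stressor of a pair, 441 to 2175 genes were called the same way and r was 0.25 to 0.62. Covariances of 0.119 to 0.491 compare with 0.0292 to 0.0298 in the simulation, which left 0.0888 to 0.461 beyond the simulated spread of the shared controls. The simulation drew DMSO libraries independently of each other. A deviation common to all 5 DMSO libraries would enter every pair, also with split controls, so it is not excluded as a source.

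Some lists were not called by camera in any comparison. All 8 tested neutrophil and granulocyte precursor genes fell at 22 h with BafA1 (list alone 0 up, 8 down, median -2.97, adjusted p 0.187). The same was seen with VPS34IN-1 (list alone 0 up, 8 down, median -3.24, adjusted p 0.173), for example Ngp (-4.48 ± 0.53) and S100a9 (-3.15 ± 0.41), and 2 of them with U18666A (list alone 0 up, 7 down). NF-kB and cytokine genes went 14 up and 5 down with BafA1 at 22 h (list alone 14 up, 6 down, adjusted p 0.43). With VPS34IN-1 they went 6 up and 18 down (list alone 6 up, 18 down, adjusted p 0.244), where Ccl3 rose (0.98 ± 0.10) and Ccl9 fell (-3.62 ± 0.15). Il1b fell at 22 h with BafA1 (-3.15 ± 0.38), U18666A (-1.94 ± 0.34), VPS34IN-1 (-3.85 ± 0.41) and MSU (-1.52 ± 0.37). Osteoclast and fusion genes split, Itgb3 rising and Dcstamp falling (-3.73 ± 0.39) with BafA1 at 22 h (3 up and 4 down of 10, list alone 3 up, 5 down, adjusted p 0.591). Phosphoinositide kinase and phosphatase genes went 6 up and 10 down of 32 with VPS34IN-1 at 22 h (list alone 6 up, 10 down). This list had a median of 0.0213, a mean of -0.0637 and a test direction of down (adjusted p 0.713). The lowest camera adjusted p was 0.32 for heat shock and 0.206 for fibroblast genes (U18666A, 7 h), 0.358 for dendritic cell genes (VPS34IN-1, 22 h) and 0.103 for mitochondrially encoded mRNAs (U18666A, 7 h). Lymphocyte, mast cell and basophil, and erythroid and platelet lists had fewer than 3 tested genes. For the called genes named here the edgeR adjusted p was at most 1.42e-07 with VPS34IN-1, 3.06e-08 with BafA1, 0.000115 with U18666A and 0.00263 with MSU, with 5 of 5 libraries on the same side.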

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

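Tests with the library-type score as a covariate on the genes called for E/L/P at 1 h, and splits that follow the library type, were chosen after the results were seen. For the other tests, what each explanation predicts was written before the test was run. Within groups of 5, a library was singled out when its gap to the nearest other library was over 0.71 of the group's range. Of 90 groups and measures of the libraries, 11 gave such a library, where chance gives about 1 in 20. U18666A 22 h replicate 3 had a total of 1.27 M counts against 5.30 to 5.71 M in the other 4 (gap 0.908 of the range) and 16470 detected genes against 21140 to 22050 (0.836). E/L/P 1 h replicate 4 had 27350 detected genes against 21150 to 22940 (0.712). The mitochondrial share was 6.56% in DMSO 1 h replicate 1 against 4.46 to 4.89% (0.795) and 3.95% in DMSO 22 h replicate 4 against 4.56 to 4.78% (0.735). VPS34IN-1 22 h replicate 1 had 20.27% of its counts in the top 20 genes against 21.86 to 22.21% (0.82). The library-type score set apart DMSO 1 h replicate 1 (-1.70 against 0.41 to 0.56, gap 0.936), VPS34IN-1 7 h replicate 2 (-0.10 against 0.40 to 0.57, 0.752) and E/L/P 7 h replicate 2 (-0.54 against 0.45 to 0.59, 0.881). It also set apart BafA1 22 h replicate 2 (-2.54 against -0.05 to 0.76, 0.752) and U18666A 22 h replicate 5 (0.14 against 0.65 to 0.72, 0.887).

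Among 28 gene levels printed above, 3 had a library that stood apart, and chance gives about 1 in 20. Acod1 was 4.64 CPM in DMSO 22 h replicate 5 against 1.59 to 2.41 CPM in the other 4 (gap 0.731). Atp1b1 was 26.8 CPM in the same library against 6.40 to 9.47 CPM (0.85), and 44.2 CPM in BafA1 22 h replicate 5 against 16.4 to 24.3 CPM (0.714). Atp1b1 was at 0 in E/L/P 22 h replicate 4 and in MSU 22 h replicate 2. The effect of each stressor differed between 1, 7 and 22 h by the edgeR interaction test, in 4171 genes for BafA1, 1943 for U18666A, 5682 for VPS34IN-1, 4037 for E/L/P and 2995 for MSU. Part of these counts may follow the uneven library types at 1 h.

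Each count of called genes was set against 100 splits of the same libraries into groups of the same sizes, the real one included. The real count and the highest of the other splits are given in that order. At 1 h they were 15 and 0 for BafA1, 6 and 1 for U18666A, 170 and 764 for VPS34IN-1, 477 and 3242 for E/L/P and 3536 and 2090 for MSU. At 7 h they were 4346 and 2375 for BafA1, 2601 and 426 for U18666A, 5546 and 2384 for VPS34IN-1, 697 and 105 for E/L/P and 3157 and 470 for MSU. At 22 h they were 5188 and 2668 for BafA1, 1564 and 645 for U18666A, 4041 and 804 for VPS34IN-1, 3032 and 63 for E/L/P and 2887 and 642 for MSU. Between stressors at 22 h they were 3925 and 2235 for BafA1 against U18666A, 2693 and 585 for BafA1 against VPS34IN-1, 4711 and 1936 for BafA1 against E/L/P, 4796 and 3385 for BafA1 against MSU, 2232 and 776 for U18666A against VPS34IN-1, 788 and 117 for U18666A against E/L/P, 2716 and 3457 for U18666A against MSU, 3248 and 120 for VPS34IN-1 against E/L/P, 4356 and 1221 for VPS34IN-1 against MSU and 3339 and 667 for E/L/P against MSU. Across times they were 4171 and 2606 for BafA1, 1943 and 878 for U18666A, 5682 and 2204 for VPS34IN-1, 4037 and 2215 for E/L/P and 2995 and 1214 for MSU. For the genes called the same way by all 5 stressors at 22 h they were 604 and 0. Here all 30 libraries were drawn into 6 groups, so drawn groups mixed stressors and DMSO. A count of 0 was therefore likely in advance, and it does not show how many genes independent responses would share. As many genes as in the real split were called by 2 of the 100 splits for VPS34IN-1 and E/L/P at 1 h, by 3 for U18666A against MSU, and by the real 1 alone elsewhere. Apart from the genes shared by all 5 stressors, these shares, taken singly, argue against a random split for each count. They were not adjusted for the number of counts. For VPS34IN-1 and E/L/P at 1 h they leave open that library types fell unevenly on the groups. For U18666A against MSU, the 2 other splits with as many genes put the 3 libraries under 2 M counts on one side, with all U18666A libraries but replicate 3 on the other. Without these 3 libraries 2085 genes were called between U18666A and MSU, 1855 of them shared with the 2716. A split of the 10 libraries by library-type score called 11 genes for BafA1 at 1 h, 0 for U18666A, 764 for VPS34IN-1, 3242 for E/L/P and 2174 for MSU. In each of these splits 1 treated library was among the 5 with the highest scores. Each was therefore the split by treatment with 1 library of each group exchanged, and its count mixes treatment with library type. The score also came from these same libraries, so the counts are no separate evidence for a library type. For VPS34IN-1 and E/L/P they were above the real 170 and 477. With the score as a covariate 280 and 193 genes were called, 165 and 141 of them shared with the genes called without it.

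The first pattern weighed was the set of 477 genes called for E/L/P at 1 h, in a comparison where 4 of 5 DMSO libraries but 1 of 5 E/L/P libraries had a higher score. A single E/L/P library was not the whole cause, since the median change of these genes was at least 0.548 (log2) without any E/L/P library, against 0.62 with all. An uneven library type may account for part of the calls. With the score as a covariate 141 of the 477 stayed called, and the median change fell from 0.62 to 0.435. Because the score was spread unevenly over the groups, the covariate also lowers the power to call genes. The number of lost calls therefore cannot show how many were due to the library type. No biological explanation was separated from the library type for the other genes of the 477.

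The second pattern was the excess of long transcripts among genes higher with MSU at 1 h (rank correlation with length 0.23 across genes). Lower depth of the MSU libraries was argued against by thinning all libraries to the same total, after which the correlation was 0.27. The library type was argued against by the covariate, with which it was 0.23. A length trend was not the whole cause of the 3536 calls, since 2810 stayed called in the same direction after each library's trend was removed. A lower yield of short transcripts and a response of short-lived or short mRNAs to MSU were not tested against each other. Length trends of the opposite sign at 22 h, -0.28 for E/L/P and -0.2 for U18666A, were not weighed in this way.

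The third pattern was the rise of hypoxia targets with BafA1. A single library was argued against, since the lowest median of the list among the 10 BafA1 libraries at 7 and 22 h was 0.959 above the DMSO mean, and a length trend was argued against, since the median at 7 h was 1 after its removal against 1.02 before. A candidate explanation is iron depletion, since the lysosomal proton gradient is needed to release iron from transferrin and HIF degradation needs iron. Tfrc, whose mRNA is stabilised by low iron, decided nothing: its lower log2 fold change of 7 and 22 h was 0.189 (7 h, not called) and at 22 h it rose (0.30), so this explanation stays open as a hypothesis.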

How the results depend on the processing

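The library-type covariate, the fits within higher-score or lower-score libraries, and the fits without libraries under 2 M counts were chosen after the results were seen, and the other settings here were planned. Of the 31 counts of called genes, all stayed within 1.5 times the reported value under RLE scaling and the stricter filter, as did the 18 fitted without libraries under 2 M counts and the 5 tests across times with all 90 libraries. DESeq2 kept 29, with 16 for U18666A and 732 for E/L/P at 1 h. No filter on low counts kept 27, with 234 for BafA1, 96 for U18666A, 279 for VPS34IN-1 and 1462 for E/L/P at 1 h, and the cause was not tested. The balance of higher and lower genes kept its direction under every setting run, fits without single libraries aside, in 3 of the 15 comparisons with DMSO (BafA1 at 7 h, E/L/P and MSU at 22 h). Among the 10 pairs of stressors it did so in 4, namely U18666A against VPS34IN-1, E/L/P and MSU, and VPS34IN-1 against E/L/P. With the replicate number as a block 30 kept, and U18666A at 1 h had 10 genes. Equal numbers were not taken to pair libraries, since the labels did not state that they shared cells. No comparison had residuals correlated above 0.1 in all 5 pairs of stressor and DMSO, a check that can miss pairing where other library differences dominate. Residuals correlated best with the library's own number for 8, 15 and 14 of 30 libraries at 1, 7 and 22 h, where chance gives 6. Structure shared by number at 7 and 22 h is therefore likely, and the main tests left it out. With the block E/L/P at 7 h had 858 genes, against 697. Fits of only the libraries compared, which estimate dispersion from fewer libraries, kept 18 of 25, with 7 for BafA1 and 44 for E/L/P at 1 h, 4691 for E/L/P at 22 h, 2546 for BafA1 against U18666A, 2841 for BafA1 against MSU, 1473 for U18666A against MSU and 5252 for VPS34IN-1 against E/L/P.

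The score covariate kept 28, with 24 for U18666A, 280 for VPS34IN-1 and 193 for E/L/P at 1 h. Groups differed in the mean score also at 22 h, for example 0.785 in E/L/P, 0.543 in DMSO and 0.415 in MSU. The covariate can therefore take out treatment effects too, and calls lost or gained with it do not show a library type alone. Higher-score libraries alone kept 27, with 182 for U18666A and 59 for E/L/P at 1 h, 229 for E/L/P at 7 h and 1186 for U18666A against E/L/P at 22 h. Lower-score libraries alone, fitted at 1 h only and with fewer libraries, gave 2 for BafA1, 1 for U18666A, 9 for VPS34IN-1, 2 for E/L/P and 746 for MSU.

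Leaving out single libraries kept 402 counts and moved 28. BafA1 at 1 h ranged from 4 to 14 (4 and 6 without DMSO replicates 4 and 5, and 6, 7 and 9 without BafA1 replicates 3, 4 and 5). Replicate 1 was the lower-score library of DMSO and the higher-score library of E/L/P at 1 h. VPS34IN-1 at 1 h ranged from 71 to 183 (112, 76, 71 and 93 without DMSO replicates 2, 3, 4 and 5, and 92, 89 and 73 without VPS34IN-1 replicates 3, 4 and 5), and E/L/P at 1 h from 109 to 1591 (1591, 208, 109, 165 and 145 without DMSO replicates 1, 2, 3, 4 and 5, and 1539, 121, 270 and 200 without E/L/P replicates 1, 2, 3 and 4). E/L/P at 7 h ranged from 365 to 772 (456 and 374 without DMSO replicates 3 and 4, 365 and 379 without E/L/P replicates 1 and 3), and U18666A against E/L/P from 463 to 820 (463 and 507 without E/L/P replicates 4 and 5, 511 without U18666A replicate 5). Genes called the same way by all 5 stressors at 22 h numbered 512 to 737.

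Of 266 pairs of named gene and comparison, all kept direction, and DESeq2, the block, no filter and the stricter filter kept every call, whereas RLE scaling ended 1, the covariate 2, fits of only the libraries compared 6, higher-score libraries alone 11 and lower-score libraries alone 28 of 38. Without some single library 11 of the pairs lost the call. Of the 80 called lists, the block ended 5 and called 11 others, the covariate ended 13 and called 4 others, and 22 lost the call without some library. The preset correlation called 53 lists more and fry 131 more. In simulated data at 22 h 67.2% of 2-fold changes were found for MSU, whose libraries averaged 2.81 M, against 86.6% for E/L/P with 5.41 M, and at 1 h MSU had the lowest recovery at 2 fold (70.1%) and 4 fold (87.9%) but the highest at 1.5 fold (47.8%).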

Other observations

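The comparisons of hypoxia targets between stressors were chosen after the BafA1 result was seen. Hypoxia targets were compared directly between BafA1 and each other stressor, over 33 tested genes. At 7 h the median log2 fold change was 0.79 against U18666A, 0.67 against VPS34IN-1, 0.97 against E/L/P and 0.83 against MSU, with 26 to 30 genes higher and 1 or 2 lower in BafA1. At 22 h it was 0.91, 0.90, 1.04 and 0.85, with 25 to 28 higher and 1 or 2 lower. The camera p adjusted over these 8 tests was 3.21e-09 to 9.74e-06 (5 libraries per group). The mitochondrial fission and mitophagy gene Bnip3 rose with BafA1 at 7 h (1.89 ± 0.09) and 22 h (1.46 ± 0.14) and fell with MSU at 22 h (-0.64 ± 0.15). Iron genes moved in both directions with BafA1 at 22 h. The importer genes Slc25a37 (2.21 ± 0.16) and Slc11a2 (1.62 ± 0.11) rose, the exporter gene Slc40a1 (-3.26 ± 0.17) and Hfe (-2.31 ± 0.13) fell. Of 17 such genes 5 went up and 5 down (list alone 5 up, 5 down, adjusted p 0.955). The edgeR adjusted p of these genes was at most 1.25e-10 for BafA1 at 22 h, 3.57e-19 for BafA1 at 7 h and 0.0018 for MSU, with 5 of 5 libraries on the same side.

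Interferon genes fell in 30 of 38 with BafA1 at 22 h (4 up, list alone 4 up, 30 down, median -1.04, adjusted p 0.127). They included Irf7 (-2.79 ± 0.30) and Oasl2 (-2.27 ± 0.17), while the GTPase gene Gbp2 rose (2.71 ± 0.21). Irf7 fell also with U18666A (-1.23 ± 0.27), VPS34IN-1 (-0.74 ± 0.25) and E/L/P (-1.15 ± 0.26). The call for VPS34IN-1 was lost in 5 of the 10 fits that left out 1 library (adjusted p 0.0512 to 0.0768). The orphan receptor gene Nr4a1 fell at 22 h with BafA1 (-4.53 ± 0.30), U18666A (-1.61 ± 0.23), VPS34IN-1 (-3.23 ± 0.26), E/L/P (-1.66 ± 0.23) and MSU (-1.12 ± 0.24). The p53 target Sesn1 fell in the same 5 comparisons (-2.46 ± 0.11, -0.91 ± 0.10, -1.97 ± 0.11, -0.55 ± 0.10 and -1.31 ± 0.11). The lipoprotein lipase gene Lpl fell with BafA1 (-3.29 ± 0.11), VPS34IN-1 (-1.85 ± 0.10), E/L/P (-0.59 ± 0.10) and U18666A (-0.47 ± 0.10) at 22 h. The fatty acid binding protein gene Fabp5 rose with these and with MSU (1.62 ± 0.10, 2.31 ± 0.10, 1.41 ± 0.10, 1.55 ± 0.10 and 0.70 ± 0.10). The edgeR adjusted p was at most 2.28e-09, 0.00146, 0.0221, 0.00122 and 0.000655 for BafA1, U18666A, VPS34IN-1, E/L/P and MSU, with 5 of 5 libraries on the same side. Lpl fell with MSU as well (-0.41 ± 0.10, adjusted p 0.00215).

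Rank correlations of fold change and transcript length across genes at 22 h were -0.063 for BafA1, -0.2 for U18666A, -0.041 for VPS34IN-1, -0.28 for E/L/P and -0.087 for MSU. That of E/L/P was larger in size than the 0.23 of MSU at 1 h, with the opposite sign. Effects of these trends on the calls and lists at 22 h were not tested. Why the number of higher-score libraries went from 14 of 30 at 1 h to 29 of 30 at 22 h was not tested.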
